A study of Mus musculus with 12 samples.

How the data were processed

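RNA from mouse neural progenitor cells of the 129/Ola strain was hybridised to 12 one-colour (Cy3) Agilent whole mouse genome arrays, 4 on each of 3 slides. Per the labels, each culture carried a retroviral open reading frame for 1 of 10 transcription factors (Pax6, Hmga2, Gatad2b, Etv6, Esx1, Nfxl1, Crebzf, Pdx1, Sox11 or Zfp451) or for EGFP, or was labelled mock. In the cultures given an open reading frame, G418, which kills cells without the vector's resistance gene, was added at 24 h, with about 95% of cells expressing the insert, and the cells were harvested at 72 h. Labelling started from 0.25 µg of RNA. Whether the mock culture met an empty virus or none, and whether it received G418, is not given in the sources used here. Each group held 1 array, so there were no replicates and no p-value was computed for any gene.

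The deposited files hold the output of Agilent Feature Extraction 10.7.3.1, and per the file headers the value of each spot is a background-subtracted intensity on the linear scale (gProcessedSignal). The deposited table of values per sample equals that column on every array and carries no further scaling. Other columns of the deposited files hold flags for outlier, saturated and well-above-background spots, which the authors' image software set. Scanner settings beyond the headers and any normalisation by the authors after image analysis are not given in the sources used here. Probe positions in the files refer to mm7.

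Spots flagged as outliers were left out and repeated spots averaged, giving 41174 probes from 43379 spots, with 245 probes spotted 10 times. Each array's log2 intensities were set relative to its 75th percentile, so a level of 0 is that percentile. Values below the lowest well-above-background signal of an array were raised to it, a floor between -7.05 and -6.46. Probes were named by RefSeq accession (23075 probes), by current symbol (6582), by synonym (3077) or as the file names them (8440). For each symbol the probe with the highest mean was used. Genes well above background on at least 1 array were kept, 20921 in all, of which 16076 were well above background on all 12. The 75th percentile of signal lay between 823.5 and 1026 units, 62.5% to 69.1% of probes were well above background, and no spot was saturated. The number of arrays limits the precision.

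Comparisons of 3 kinds were fixed before the data were examined, with the gene lists, the rule for naming genes and most alternatives. First, a gene was called on a factor's array when its level was at least 2-fold above, or at least 2-fold below, both the EGFP and the mock array, with the brighter side well above background. The same 2 controls served all 10 factors, so noise in a control enters every factor's calls. Second, a gene was specific to an array when it was at least 2-fold above, or below, each of the other 11 arrays. Last, 33 gene lists (neural and glial cell types, other cell types the culture could hold, stress, growth, signalling, patterning and control genes) were compared with 10000 random lists matched for level in 20 bins. A list was called when its median difference from the control mean lay at or above the 97.5th or at or below the 2.5th percentile of those medians. Members of a list move together in cells, which random lists do not reproduce, so these percentiles are not p-values.

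Sizes are differences from the mean of both controls in log2, or folds. A fold is written as at least a value when the dimmer side, or either control on it, was not well above background. The text names, for each array, the 8 called genes in each direction with the largest smaller of both differences, unless another probe of the gene opposed it, called members of called lists, the overexpressed genes, and up to 10 genes called on the most factor arrays. Clones, predicted genes and olfactory or vomeronasal receptors were left out of the naming. Genes named beyond this rule are marked as chosen after their values were seen.

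The rules were tested on simulated data. Noise was drawn from the differences between the EGFP and mock arrays, which stood on 1 slide, so it holds no differences between slides. In 20 sets of unchanged arrays, a median of 176 genes, and at most 229, met the rule for calls. A median of 62, at most 87, met the rule for specific genes. On a simulated Sox11 array of 20921 genes, 200 changed genes were placed, all drawn from the 16076 well above background on all 12 arrays. Of those with a log2 change of 1.0, 20.0% were called, and of those with 1.5, 100%. None with 0.58 was called. Recovery of dimmer genes was not tested.

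Alternatives were quantile normalization, a normexp background correction (offset 50), no floor, the mean of all probes of a gene, centring within slides, only genes well above background on all 12 arrays, a 3-fold rule, each control alone, and the median of the other 9 factor arrays as reference. Chosen after seeing the data were a 1.5-fold rule for specific genes, counts of list members highest or lowest of the 12 arrays, counts of genes at least 2-fold apart in each of the 66 pairs of arrays, imprinted and sex-linked gene lists, and leaving out genes shared by slide 2. Slide 1 held the mock, EGFP, Pax6 and Hmga2 arrays, slide 2 the Gatad2b, Etv6, Esx1 and Nfxl1 arrays, and slide 3 the Pdx1, Sox11, Crebzf and Zfp451 arrays. Each slide was scanned in a run of its own. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.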

Results

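Expression was measured in neural progenitor cells that overexpressed 1 of 10 transcription factors, beside an EGFP and a mock control, with 1 array for each. The series names 6 factors as interfering and 5 as non-interfering, but the labels give 10 factors and do not say which is which, so no comparison between those kinds was made. The question addressed here was which genes differed from both controls on each factor's array. There are no replicates, so every value below rests on 1 array for each factor and sizes carry no error of their own. Between both controls, among the 16076 genes well above background on all 12 arrays, the median absolute log2 difference was 0.07 and 42 genes differed at least 2-fold. Of these, 41 lay in the dimmest of 3 equal parts of the genes.

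The overexpressed genes themselves were examined first. None of their 26 probes was at least 2-fold above every other array on the array of its own factor, and 3 were the highest of the 12. A retroviral insert carries only the open reading frame, and which probes lie inside it was not established here, so these values do not check the array labels in either direction. The 3 probes of Pax6, a regulator of eye and forebrain development on chromosome 2, stood 1.34, at least 0.96 and 1.35 log2 above the control mean on the Pax6 array. The second was well above background on 2 arrays and at the floor on EGFP. Their ranks from the highest were 6, 1 and 4, and Pax6 was called higher on 6 factor arrays, by 1.34 to 1.77, with its own array the lowest of them. The first probe lies at positions 105547907 to 105547966 in mm7. The Hmga2 probes, for a chromatin protein of embryonic cells, differed by -0.03, 0.20 and -0.16, and the Etv6 probes by -0.20 and 0.34. The Esx1 probe on chromosome X stood at -0.83 and the Crebzf probe at -0.15. The 6 Sox11 probes lay between -0.40 and 0.32, and the 4 Zfp451 probes between -0.39 and 0.02. Gatad2b gave 0.02, -0.04 and -0.07, and Nfxl1 0.10 and -0.07. Pdx1 was well above background on no array.

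The 12 arrays fell into 2 sets of 6. One held the Pax6, Esx1, Crebzf, Pdx1, Sox11 and Zfp451 arrays, and the other held both controls with Hmga2, Gatad2b, Etv6 and Nfxl1. Across the sets, 3854 to 4986 genes differed at least 2-fold in each of the 36 pairs of arrays. Within them the 15 pairs of the first set differed at 143 to 1357 genes and the 15 of the second at 303 to 839. The 6 pairs that crossed the sets on 1 slide differed at 4144 to 4505 genes. This count and this division were chosen after the data were seen, and the sets are not groups of the study.

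**Figure D1:**
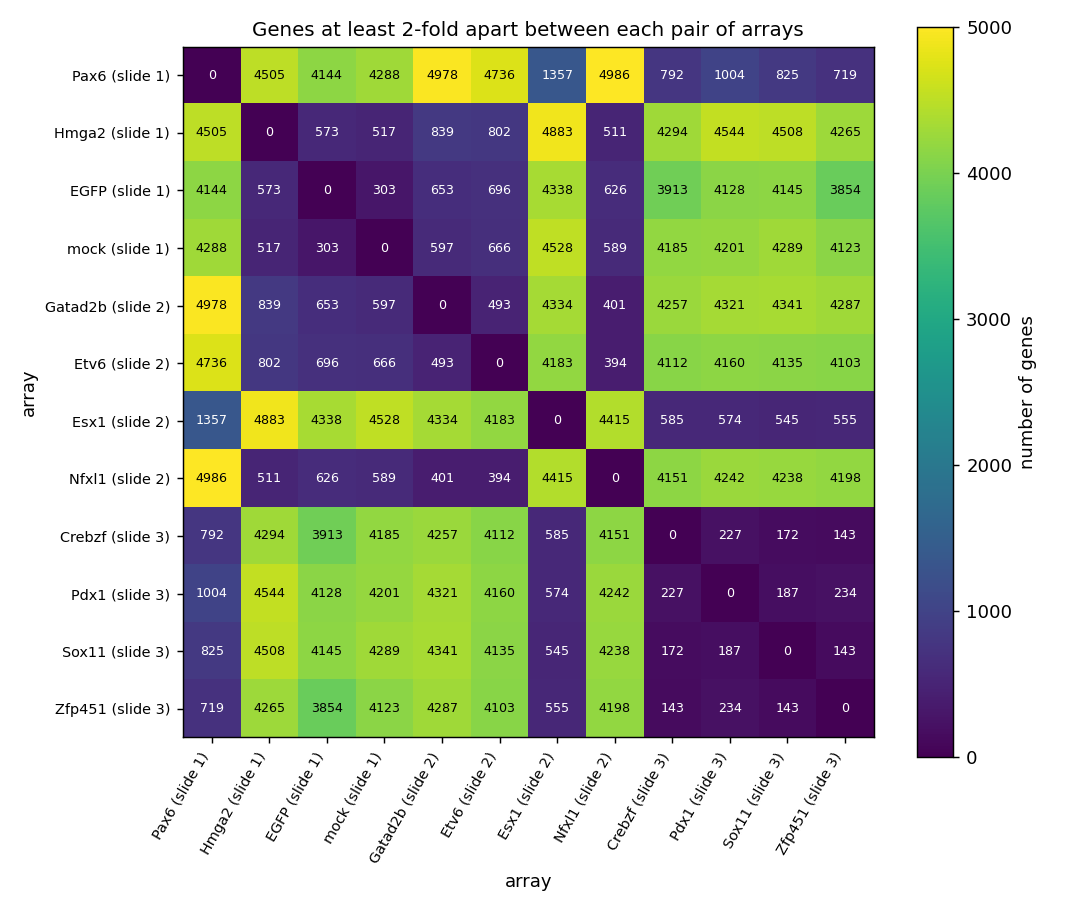
Heat map of the number of genes at least 2-fold apart in each pair of the 12 arrays, with arrays on both axes and the count in each cell. Pairs within a set of 6 lie at or below 1357 genes and pairs across the sets at or above 3854.

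Against both controls, between 3324 and 3713 genes were called on each array of the first set, of 20921 tested, and between 234 and 391 on each of the other 4 factor arrays. Pax6 had 2239 genes higher and 1342 lower, Esx1 2161 and 1552, Crebzf 2051 and 1317, Pdx1 2058 and 1389, Sox11 2036 and 1452, and Zfp451 2005 and 1319. Etv6 had 216 higher and 175 lower, Gatad2b 135 and 219, Nfxl1 61 and 256, and Hmga2 91 and 143. Among genes well above background on all 12 arrays, Gatad2b had 14 higher and 154 lower, Etv6 121 and 131, and Nfxl1 9 and 163. Simulated unchanged arrays gave up to 229 calls, so the Hmga2 count of 234 lay just above that range. The median of the 16076 genes well above background on all 12 arrays moved by -0.13 on Esx1, Pdx1 and Sox11. It moved by -0.12 on Crebzf and Zfp451 and by -0.06 on Pax6, and the sizes below are not corrected for this shift.

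**Figure D2:**
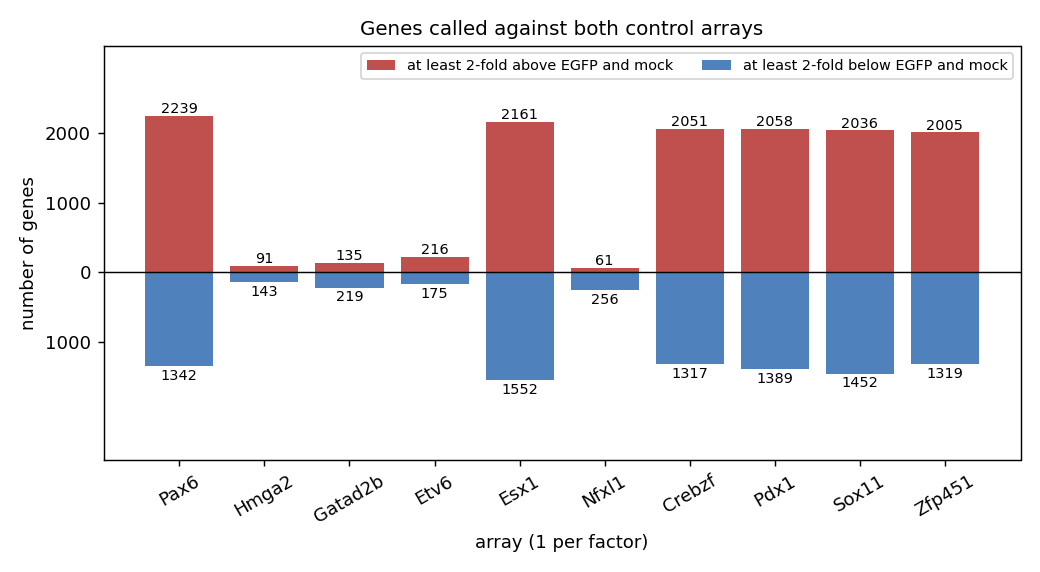
Bars of the number of genes called higher and lower than both controls on each factor's array, 1 array each, from 0. Counts run from 234 on the Hmga2 array to 3713 on the Esx1 array.

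On all 6 arrays of the first set, 2084 genes were called in the same direction, 1407 higher and 677 lower. No other choice of 6 among the 10 factor arrays shared more than 59. Postn, an extracellular matrix protein, was 78.8-fold to 144-fold higher across the 6, and Meg3, a maternally expressed long noncoding RNA, 28.6-fold to 110-fold. Islr was at least 43.6-fold to 61.4-fold higher and Vill 28.2-fold to 42.9-fold. Among the lower genes, Padi2, which converts arginine to citrulline in proteins, was 14.5-fold to 24.9-fold lower. Mcpt8, a mast cell and basophil protease, was 12.2-fold lower on the Pax6 array and at least 15.9-fold to 20.1-fold lower on the others.

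The fibroblast and astrocyte lists were called on all 6 of these arrays. Of 14 fibroblast and extracellular matrix genes measured, 7 to 10 rose, with list medians of 1.01 (Pax6) to 1.34 (Pdx1) log2. Lox, which cross-links collagen, was 10.2-fold to 16.2-fold higher, Col1a1 4.3-fold to 4.9-fold and the proteoglycan gene Dcn 4.0-fold to 9.3-fold. Of 11 astrocyte genes, 4 to 7 rose, with medians of 0.92 to 1.19. Apoe, a lipid carrier, was 5.3-fold to 9.6-fold higher and the calcium-binding S100b 2.4-fold to 3.8-fold. The muscle list was called on the Esx1 and Pdx1 arrays (medians 0.77 and 0.51), where the actin gene Acta1 was 3.3-fold and 3.5-fold higher and Tnnt2 5.8-fold and 5.4-fold lower.

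Of 18 TGF-beta and BMP genes, 7 rose on each of the 6 arrays, with medians of 0.42 to 0.58. Id2, an inhibitor of basic helix-loop-helix factors, was 9.3-fold to 12.8-fold higher, and the growth factor Bmp4 4.0-fold to 4.6-fold. Of 21 Hox genes, which set position along the body axis, 9 or 10 rose on the Esx1, Crebzf, Pdx1, Sox11 and Zfp451 arrays, with medians of 0.70 to 1.17. Hoxa10 was 7.3-fold to 9.1-fold higher on those 5 and Hoxb2 at least 6.1-fold to 7.5-fold. On the Pax6 array the Hox median of 0.54 did not pass (percentile 96.7). The inflammation list was called on Pax6, Crebzf, Pdx1, Sox11 and Zfp451 (medians 0.34 to 0.56), with 4 of 12 genes higher, among them the adhesion molecule Icam1 at 5.3-fold to 10.7-fold. After normexp correction the Hox medians were 0.15 to 0.38, and the muscle median on Esx1 was 0.46.

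The cell cycle list fell on all 6 arrays. Of 26 cell cycle genes, 5 to 10 fell, with medians of -0.95 (Pax6) to -0.75 (Zfp451). Ccne1, a cyclin of the start of DNA replication, was 3.0-fold to 3.6-fold lower, and the mitotic kinase Plk1 2.3-fold to 3.2-fold. The senescence list was called on Esx1, Crebzf, Pdx1, Sox11 and Zfp451 (medians 0.36 to 0.61), with 1 or 2 of 11 genes called, and its medians were 0.21 to 0.36 with normexp correction. Cdkn1c, a cyclin-dependent kinase inhibitor, was at least 8.6-fold to 17.2-fold higher on those arrays. The hypoxia list was called on Crebzf, Pdx1, Sox11 and Zfp451 (medians 0.18 to 0.39), where the mitophagy receptor Bnip3 was 3.6-fold to 4.2-fold higher, and its medians were 0.13 to 0.31 with normexp. The list of let-7 targets and partners of Hmga2 fell on those 4 arrays (medians -0.58 to -0.55). Of its 13 genes, 2 or 3 were called lower on each and 2 higher, Plagl1 and Igf2, the latter by 10.3-fold to 12.2-fold.

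The slides bear on these values. Pax6 stood on the controls' slide, so its count of 3581 is a within-slide value, and Esx1 stood with 3 arrays of the other set and had 3450 calls when values were centred within slides. The 4 arrays of slide 3 all lay in the first set, and centring there removes what they share, leaving 95 (Crebzf), 79 (Pdx1), 65 (Sox11) and 57 (Zfp451) calls. Centred medians of the other lists called on slide 3 were at most 0.33 for astrocyte, 0.18 for TGF-beta and BMP, 0.24 for Hox, 0.25 for inflammation, 0.09 for senescence and 0.12 for hypoxia genes, and at lowest -0.15 for let-7 targets. Centred interferon medians were 1.65 on Esx1 and 0.38 to 0.67 on slide 3, fibroblast medians 1.10 and 0.26 to 0.28, and cell cycle medians -0.82 and -0.27 to -0.21. On Pdx1, centring turned the muscle median to -0.02 and the hypoxia median to -0.09, and Cdkn1c turned to -0.35 there and -0.07 on Sox11. Centring subtracts each slide's mean, and that of slide 1 holds the Pax6 array beside both controls. A share of the Pax6 difference thus enters every centred value on slides 2 and 3. A centred list median on slide 3 therefore does not show that those arrays keep a difference of their own. Each of the 4 arrays of slide 3 shared 2514 to 2595 calls, in the same direction, with the Pax6 array of the controls' slide. Independent calls at the same counts would share 299.2 to 311.0, an expectation that leaves out the shared controls. Simulated unchanged arrays with shared controls shared a mean of 13.9, but carried far fewer calls. For calls that the arrays of slide 3 share with neither the Pax6 nor the Esx1 array, slide and factor cannot be told apart.

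Interferon response genes had their highest list median, 2.16 log2, on the Pax6 array, where 18 of 21 measured rose. Ifit3 was 17.5-fold higher, Ifi44 13.8-fold, the protease Usp18 12.5-fold and the antiviral GTPase gene Mx2 11.6-fold. The other arrays of the first set had medians of 1.13 to 1.28 with 10 to 13 genes higher. With normexp correction the Pax6 median was 1.32 and the Pdx1 median 0.79.

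**Figure D3:**
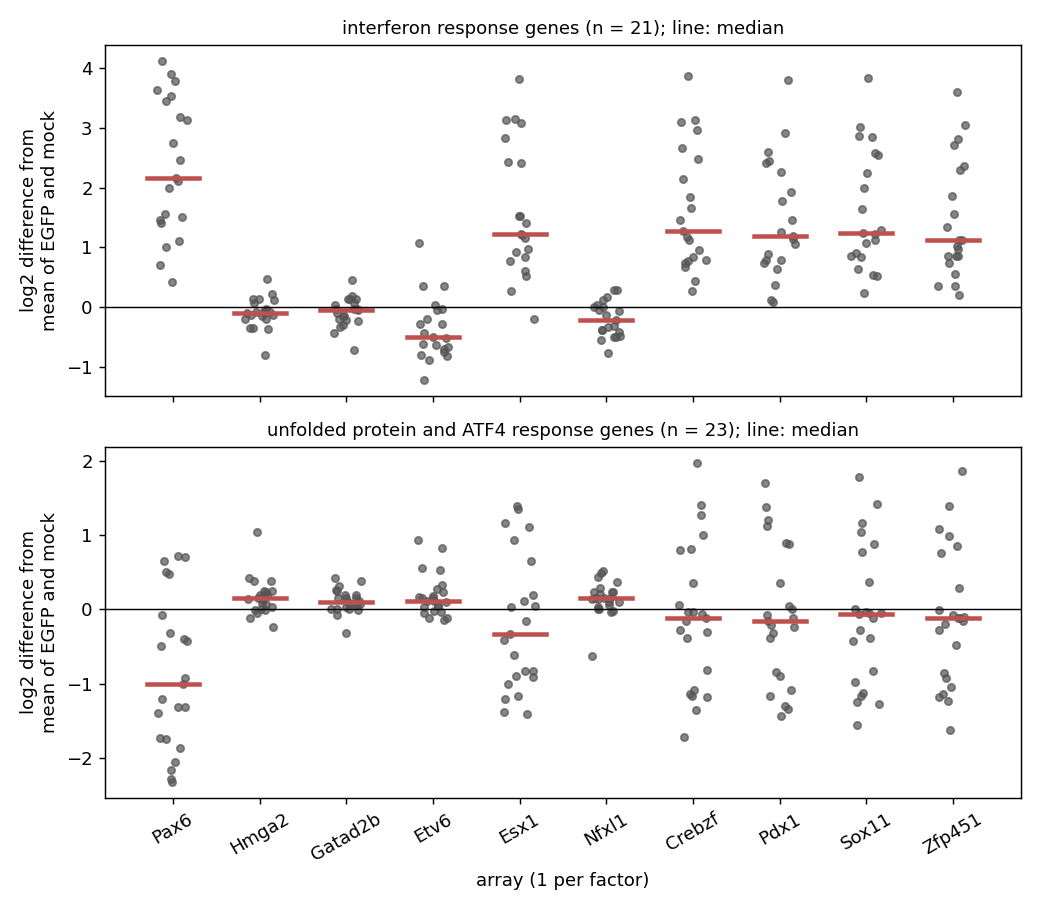
Log2 difference from the control mean of each interferon response gene and each unfolded protein and ATF4 response gene on each factor's array, with 1 point for each gene and a line at the list median. The interferon median is 2.16 on the Pax6 array and -0.50 on the Etv6 array, and the ATF4 median is -1.01 on the Pax6 array.

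Of 23 unfolded protein and ATF4 response genes, 11 fell on the Pax6 array, with a median of -1.01, while Ddit3 stood at 0.71 and Herpud1 at 0.72. Mthfd2, of mitochondrial folate metabolism, was 5.0-fold lower, the cystine transporter Slc7a11 4.8-fold, the serine enzymes Shmt2 4.5-fold and Psat1 3.6-fold, and the asparagine synthetase gene Asns 3.3-fold. Slc7a11, Shmt2 and Psat1 were called lower on the other 5 arrays of the set as well, where 4 to 6 members were lower and 3 or 4 higher, and where the list medians of -0.33 to -0.06 did not pass. Of 10 replication-dependent histone genes 2 fell and 1 rose, with a median of -0.70. The Pax6 array had 92 specific genes, 84 higher and 8 lower, against 53 on EGFP, 79 on mock and up to 87 on simulated unchanged arrays. Fos, an immediate early transcription factor, stood at 0.98 there and between -4.77 and -1.43 on the other 11 arrays.

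The Esx1 array had 86 specific genes, 49 higher and 37 lower. Among those lower, and chosen after their values were seen, the arginine methyltransferase gene Prmt1 was 6.1-fold below the controls and the lamin gene Lmnb1 5.2-fold. Below the nearest other array they stood by less, 1.52 and 1.38 log2. Other probes of the lower genes were below all 11 arrays in 8 of 18 cases. The Crebzf, Pdx1, Sox11 and Zfp451 arrays had 55, 47, 35 and 32 specific genes, all higher, and differed from one another at 143 to 234 genes, fewer than the 303 between both controls.

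The Etv6 array carried 391 calls. Tbc1d30 was at least 32.9-fold higher, the keratin gene Krt76 17.3-fold, the ferritin receptor Scara5 15.3-fold and Akr1c18, which inactivates progesterone, 13.0-fold. Of 10 epithelial genes, 3 rose, the keratins Krt8 3.1-fold and Krt18 2.1-fold and the tight junction gene Cldn6 2.4-fold, with a median of 0.67. The interferon list had a median of -0.50, with Oasl2 2.3-fold lower, and the oligodendrocyte list a median of -0.45, with Pdgfra 2.3-fold higher. The cell cycle median was -0.09 and the ATF4 median 0.12, both called with no member called. All 99 genes specific to Etv6 were higher, and 11 of 13 other probes of them were also above all 11 arrays. Centred within slides, 121 calls were left, the interferon median was -0.11, the epithelial 0.39, the ATF4 -0.05, the cell cycle -0.15 and the oligodendrocyte -0.02. Those centred values also carry shares of the Pax6 and Esx1 differences, since these 2 arrays enter the means of slides 1 and 2. With normexp the oligodendrocyte median was -0.11, the interferon -0.27 and the epithelial 0.33. The share of higher genes, 55.2%, was 69.9% with quantile normalization, 43.4% with no floor, 48.0% for genes well above background on all 12 arrays, and 46.8% and 41.0% against EGFP or mock alone.

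On the Gatad2b array, Nab2, a repressor of early growth response factors, was 3.9-fold lower. Spry4, a feedback inhibitor of growth factor signalling, was 5.0-fold lower there and was called lower on the 4 arrays of slide 2 and on no other factor array. Defb6, a defensin, was at least 16.2-fold higher and Ferd3l at least 10.8-fold. None of the 8 largest rises began well above background in both controls. The inflammation list had a median of 0.20, the FGF list -0.03 and the oligodendrocyte list -0.29, which centring within slides brought to 0.06, -0.04 and -0.05. Spry4 was the only called member of these lists. The array had 111 specific genes, of which 98 were higher. On the Nfxl1 array, Cx3cr1, the fractalkine receptor, was at least 11.1-fold higher and Galnt14 at least 7.6-fold lower. Its lists were called with no member called: heat shock 0.17, ATF4 0.15, inflammation 0.12, p53 targets 0.09, epithelial 0.08, astrocyte -0.09, interferon -0.22 and oligodendrocyte -0.39. Nfxl1 had 38 specific genes, Cx3cr1 among them, against 53 on EGFP and 79 on mock. Centred within slides, 99 calls were left on Gatad2b and 90 on Nfxl1, and on Nfxl1 the interferon median turned to 0.13, the epithelial to -0.24, the inflammation to -0.03 and the ATF4 to -0.06, while the oligodendrocyte was -0.18 and the p53 median 0.01. With quantile normalization the share of higher genes was 52.8% in place of 38.1% on Gatad2b, and Nfxl1 had 109 higher and 109 lower.

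A block of lower genes was shared along slide 2. The Gatad2b, Etv6 and Nfxl1 arrays had 73 called genes in common, all lower, and 61 of these were also called lower on the Esx1 array of that slide. Arrays of other slides called 3 to 11 of them. Smg8, of nonsense-mediated decay, was at least 7.8-fold lower on Gatad2b, at least 6.7-fold on Etv6 and 4.0-fold on Nfxl1, and Cep20 and Hacl1 belong to the same block. Centred within slides, Smg8 stood at 0.03 on Etv6 and 0.77 on Nfxl1. Without the 61 genes, 293 calls were left on Gatad2b, 330 on Etv6 and 256 on Nfxl1.

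On the Hmga2 array, Sox6, a transcription factor of neural and cartilage cells, was at least 13.8-fold higher, S1pr4 at least 20.6-fold and Zan at least 17.4-fold. Galnt14 was at least 10.4-fold lower, the homeobox gene Nkx1-2 at least 6.8-fold and Foxp2 at least 4.0-fold. The fibroblast list had a median of -0.15, with Postn 2.4-fold lower. The ATF4 list (0.15), the histone list (0.14) and the endothelial list (0.26) were called with no member called. Hmga2 had 42 specific genes, S1pr4 and Zan among them, against 53 on EGFP, 79 on mock and a median of 62 on simulated unchanged arrays. Rises of dim genes on 1 array alone thus met this rule at least as often on the controls. Normexp correction left 15 calls and an endothelial median of 0.01.

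Ceacam19, a cell adhesion gene, was lower on all 10 factor arrays, and Gpr101 on 9. Ceacam19 was well above background on 3 arrays only, so its falls are lower limits, such as at least 8.6-fold on Hmga2. E2f4, a cell cycle repressor, was lower on 8 (-2.60 to -1.17). In simulated arrays, which share their controls in the same way, up to 2 genes were called on all 10, up to 6 on at least 9 and up to 8 on at least 8, where the data had 1, 4 and 10. The EGFP array differed from mock by list medians of 0.13 for interferon, -0.08 for ATF4, 0.15 for muscle, -0.07 for FGF and -0.05 for p53 targets.

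Of the 33 lists, 14 were called on no factor array. Their percentiles ran from 5.7 to 72.1 for neural progenitor, 7.2 to 90.5 for neuronal differentiation, 29.4 to 96.1 for pluripotency and 33.6 to 94.3 for microglia. They ran from 3.2 to 39.8 for pancreatic islet, 15.7 to 54.5 for lens and eye, 7.9 to 89.5 for placenta and 4.8 to 45.4 for cholesterol synthesis. For Notch they were 16.3 to 79.5, Wnt 7.0 to 95.2, hedgehog 7.0 to 62.6, forebrain 14.5 to 91.9, ribosomal protein 55.0 to 93.5 and common control genes 5.9 to 78.5. Single neural genes did pass, and were picked after their values were seen. Stmn2, a microtubule regulator of neurons, was 2.61 to 4.24 log2 higher on the 6 arrays of the first set and Snap25, of synaptic vesicle release, 2.44 to 3.22, while Nefl, a neuronal filament gene, was lower on 5 of them (-2.76 to -0.76 over the 6). Among progenitor genes, Nes, a filament gene, was lower on 5 (-1.51 to -1.08), and the transcription factor genes Sox9 (up to 2.69) and Lhx2 (up to 1.64) were higher on 5 and Pax6 on 6. In all, 77 of 330 list values passed, where 16.5 would if list members moved together no more than matched random genes. Members do move together, all factor arrays share their controls, and the 6 arrays of the first set resemble one another. No test is drawn from these counts.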

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

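Of the tests in this part, only that of the sex of the cells was set before its result was seen, and all others were chosen after it. Each of these list differences was picked because both arrays' list medians passed a bound in opposite directions, and none was tested as a difference, since each array stands alone. Interferon response genes differed by 2.66 log2 between the Pax6 and Etv6 arrays. Their medians were 1.32 and -0.27 with normexp correction, and 2.16 and -0.11 when centred within slides. Fibroblast and extracellular matrix genes differed by 1.49 between the Pdx1 and Hmga2 arrays, and astrocyte genes by 1.28 between Sox11 and Nfxl1. Each of these pairs lies on different slides. Centred within slides, the fibroblast medians were 0.28 on Pdx1 and -0.15 on Hmga2, and the astrocyte medians 0.33 on Sox11 and -0.09 on Nfxl1. Unfolded protein and ATF4 response genes differed by 1.16 between Nfxl1 and Pax6, and replication-dependent histone genes by 0.84 between Hmga2 and Pax6. Centred within slides, the ATF4 medians were -0.06 on Nfxl1 and -1.01 on Pax6. Centring cannot change the Pax6 or Hmga2 values, since those arrays share slide 1 with both controls. A share of the Pax6 difference enters the mean of slide 1, and so every centred value on slides 2 and 3. What centring does to these list differences therefore does not separate slide from factor.

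The split of the 12 arrays into 6 and 6 was weighed against the slide or scan run, cells of the other sex, and a minor share of other cells mixed in. Arrays on 1 slide but on different sides differed at no fewer than 4144 genes, above the 1357 of the most distant pair on 1 side, so slide or scan run alone does not account for it. For cells of the other sex, 2 Y-linked genes, Ddx3y and Eif2s3y, were well above background on all 12 arrays, which cells without a Y chromosome forbid; both were slightly higher on the 6 arrays (0.16 to 0.43 against -0.29 to -0.11 for Ddx3y and 0.99 to 1.17 against 0.45 to 0.84 for Eif2s3y), as was Uty (-5.06 to -4.47 against -6.68 to -5.26, well above background on 10 arrays), so the overlap that the test had set beforehand held for Xist (-6.96 to -3.80 against -7.05 to -4.47) and not for these. For a minor share of other cells on the 6 arrays, 57 genes were at least 4-fold below both controls on each of them. A minor share of the RNA there cannot bring that about. For a minor share in the controls instead, 426 genes were at least 4-fold above both controls on each of the 6. Such a share cannot bring that about either. What stays open, untested, is whether the factors, or a different culture or cell population behind those arrays, may lie behind the split, since each factor has 1 array.

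The lower genes shared by the Gatad2b, Etv6 and Nfxl1 arrays were weighed against slide or scan run. Of the 73, 61 were also called on the Esx1 array of the same slide, which lies on the other side of the split, against at most 11 on an array of another slide. That is consistent with an effect of slide 2, and a shared effect of those 4 factors was not tested.

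That the overexpressed genes did not stand out on their own arrays was weighed against probes outside the inserted reading frame and array labels in another order. Of 4 intron-spanning probes, 0 stood at least 2-fold above every other array on the own array, and 0 of all probes did so on an array with another label. Labels in another order would move a raised signal to another array, and none of the 26 probes was so raised on any array. Label order alone therefore does not account for the pattern. Probes outside the reading frame stay open, since no probe could be placed inside or outside an insert. Whether the labels are in order stays open for the same reason.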

How the results depend on the processing

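The 1.5-fold rule and the setting without genes shared by slide 2 were chosen after seeing the data, and all other settings were planned. No paired analysis was possible because each group holds 1 array. The planned use of the deposited value table gave nothing new, because it is identical to the processed signal. Signal over background limits dim genes: of 3 equal parts of the genes by level, the dimmest held 41 that differed 2-fold between both controls and the brightest 0. Quantile normalization and the mean of all probes of a gene moved no total of calls or of specific genes by more than 1.5 times, though quantile normalization moved the split of calls by direction further. Leaving out the slide 2 genes, run for the calls of the 4 arrays of that slide alone, moved none of those by that much. Leaving out either control moved no count of specific genes by that much. Where no reason is stated, the cause was not tested.

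Counts of calls were as follows. With normexp background correction they were 2087 on Pax6, 15 on Hmga2, 74 on Gatad2b, 128 on Etv6, 2150 on Esx1, 46 on Nfxl1, 1885 on Crebzf, 1917 on Pdx1, 1877 on Sox11 and 1855 on Zfp451. Of these, 2083 on Pax6 and 2144 on Esx1 were among the calls reported. At 3-fold, where fewer pass by construction, they were 1407 on Pax6, 54 on Hmga2, 125 on Gatad2b, 129 on Etv6, 1558 on Esx1, 70 on Nfxl1, 1382 on Crebzf, 1381 on Pdx1, 1391 on Sox11 and 1338 on Zfp451. Against the median of the other 9 factor arrays they were 711 on Pax6, 3674 on Hmga2, 3593 on Gatad2b, 3480 on Etv6, 634 on Esx1, 3633 on Nfxl1, 344 on Crebzf, 361 on Pdx1, 316 on Sox11 and 303 on Zfp451. That reference is a median dominated by the first set of arrays, which makes the other factors differ. With no floor, counts were 362 on Hmga2 and 616 on Nfxl1. For genes well above background on all 12 arrays, a smaller set, they were 77 on Hmga2, 168 on Gatad2b, 252 on Etv6 and 172 on Nfxl1. Against EGFP alone, an easier rule, they were 573 on Hmga2, 653 on Gatad2b, 696 on Etv6 and 626 on Nfxl1, and against mock alone 517, 597, 666 and 589. Centred within slides they were 99 on Gatad2b, 121 on Etv6, 90 on Nfxl1, 95 on Crebzf, 79 on Pdx1, 65 on Sox11 and 57 on Zfp451. For the last 4 this follows from construction, since slide 3 holds arrays of 1 side of the split only.

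Counts of specific genes were as follows. With normexp they were 26 on Pax6, 5 on Hmga2, 9 on Gatad2b, 36 on Etv6, 32 on Esx1, 4 on Nfxl1, 4 on EGFP, 9 on Crebzf, 7 on Pdx1, 6 on Sox11, 1 on Zfp451 and 6 on mock. For genes well above background on all 12 arrays they were 27 on Pax6, 7 on Hmga2, 13 on Gatad2b, 30 on Etv6, 45 on Esx1, 5 on Nfxl1, 4 on EGFP, 6 on Crebzf, 2 on Pdx1, 4 on Sox11, 2 on Zfp451 and 3 on mock. At 3-fold they were 42 on Pax6, 19 on Hmga2, 45 on Gatad2b, 51 on Etv6, 33 on Esx1, 20 on Nfxl1, 31 on EGFP, 33 on Crebzf, 24 on Pdx1, 22 on Sox11, 17 on Zfp451 and 43 on mock. At 1.5-fold they were 367 on Pax6, 88 on Hmga2, 202 on Gatad2b, 221 on Etv6, 267 on Esx1, 82 on Nfxl1, 120 on EGFP, 58 on Sox11 and 136 on mock. With no floor they were 65 on Hmga2, 67 on Nfxl1, 155 on EGFP, 56 on Sox11 and 55 on Zfp451. Centred within slides they were 24 on Hmga2, 67 on Gatad2b and 143 on Esx1.

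Signs turned under slide centring only. Cep20 became 0.12 on Gatad2b and 0.34 on Etv6, Smg8 0.03 on Etv6 and 0.77 on Nfxl1, Hacl1 0.18 and Spry4 0.24 on Etv6. Hoxd9 became -0.03 on Crebzf, -0.15 on Sox11 and -0.02 on Zfp451, and Cdkn1c -0.35 on Pdx1 and -0.07 on Sox11. The muscle median became -0.02 and the hypoxia median -0.09 on Pdx1. On Nfxl1 the epithelial median became -0.24, the interferon median 0.13, the inflammation median -0.03 and the unfolded protein and ATF4 median -0.06, and on Etv6 the last became -0.05. With normexp the endothelial median on Hmga2 became 0.01, the oligodendrocyte median -0.04 on Gatad2b and -0.18 on Nfxl1, and the epithelial median 0.03 and the p53 median 0.05 on Nfxl1. With quantile normalization the medians on Nfxl1 were 0.36 for epithelial, 0.09 for heat shock, -0.10 for interferon and -0.18 for oligodendrocyte genes. Under slide centring the other list medians held their sign, except the senescence median on Zfp451, which vanished. Medians on the Pax6 and Hmga2 arrays could not change, since those arrays share a slide with both controls. Every centred value on the other slides carries a share of the Pax6 difference. A sign that held or turned there therefore does not separate slide from factor.

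Scaling and filtering also moved the share of called genes that were higher. With quantile normalization it was 69.9% in place of 55.2% on Etv6, 52.8% in place of 38.1% on Gatad2b, and 49.0% in place of 38.9% on Hmga2, and Nfxl1 had 109 higher and 109 lower in place of 61 and 256. Centred within slides it was 95.9% on Etv6, 88.9% on Gatad2b, 58.9% on Nfxl1, 87.4% on Crebzf, 72.2% on Pdx1, 80.0% on Sox11 and 77.2% on Zfp451. With normexp it was 73.3% on Hmga2 and 17.6% on Gatad2b, and for genes well above background on all 12 arrays 8.3% on Gatad2b and 5.2% on Nfxl1. On Etv6 it was 43.4% with no floor, 48.0% for genes well above background on all 12 arrays, 46.8% against EGFP alone and 41.0% against mock alone, which gave 26.5% on Gatad2b. The median of genes well above background on all 12 arrays was -0.12 on Crebzf, -0.08 after quantile normalization and -0.01 after slide centring.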

Other observations

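The counts and lists in this part were chosen after the data were seen, and their values are given without explanation. Imprinted genes, expressed from 1 parental copy, were among the largest rises. Of 43 listed, 38 were measured, and 15 or 16 rose on each of the Pax6, Esx1, Crebzf, Pdx1, Sox11 and Zfp451 arrays, with list medians of 0.60 to 0.67 log2, while 2 fell on Pax6 and 1 on Zfp451. Meg3, Rian, Dlk1, Igf2, Grb10, Peg3 and Magel2 were called on all of them. Meg3 stood at levels of 1.35 to 3.29 there and -3.87 to -3.11 on the other 6 arrays. Igf2, a fetal growth factor, stood at 1.82 to 2.28 against -1.88 to -1.28, and Peg3 at -0.42 to 0.26 against -3.96 to -3.38. Magel2 stood at -1.18 to -0.37 against -5.51 to -4.67. Others differed little: Snrpn stood at -0.59 to -0.40 against -0.85 to -0.45, and Ube3a at 2.82 to 3.39 against 2.92 to 3.54. Cdkn1c was called on 5 of those arrays and was at -6.70 on Pax6. The imprinted median was 0.15 on Etv6, with 3 genes higher, -0.10 on Hmga2, 0.04 on Gatad2b and -0.04 on Nfxl1.

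Some lists stood at an end of the 12 arrays gene by gene. On the Pax6 array 18 of 26 cell cycle genes, among them Mki67 and Top2a, and 16 of 23 unfolded protein and ATF4 response genes were the lowest of all arrays, and 19 of 21 interferon response genes the highest. On the Etv6 array 10 of 21 interferon response genes, among them Ifit1 and Isg15, were the lowest, and 4 of 10 epithelial genes, Epcam, Krt7, Krt8 and Krt18, the highest. The Hmga2 array was lowest in 7 of 14 fibroblast and extracellular matrix genes, and the Esx1 array highest in 8 of 14 and in 9 of 21 Hox genes.

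Xist, the RNA that silences an X chromosome, was well above background on 3 arrays. The Y-linked gene Uty was so on 10, and 3 of 4 listed Y-linked genes were measured.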
